A study of Arabidopsis thaliana with 12 samples.

How the data were processed

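RNA of 12-day-old Arabidopsis thaliana Col-0 seedlings was measured by NAD tagSeq. There the enzyme adenosine diphosphate ribosylcyclase (ADPRC) lets a synthetic tag RNA be joined to transcripts that carry NAD+ in place of the usual cap. RNA molecules are then read on a Nanopore instrument. Reactions without ADPRC were the background control. The 12 libraries fall into 6 groups by the RNA used (poly(A) RNA or total RNA), the ADPRC reaction and the enrichment of tagged molecules. Enriched poly(A) RNA was read in 3 libraries with and 3 without ADPRC, unenriched poly(A) RNA in 3 libraries with and 1 without ADPRC, and enriched total RNA in 1 library of each kind. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of replicates matched within sampling noise: a chi-square statistic per gene ran from 1.20 to 4.76.

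The authors deposited a table of tagged reads, called NAD-RNA, and a table of all reads, each with a value per gene and library under the name TPM, per the file headers. In these data the deposited values behave as CPM, relative to all reads of the library and without a correction for transcript length, and both tables share the library's total of all reads as denominator. Every one of the 38774 tagged values and the 177709 all-read values above 0 was a whole multiple of the value of 1 read, within a tolerance of 0.01 reads (100%), so whole reads were recovered. The unit is written TPM below, as the files name it. The base caller, aligner, genome build, annotation, strand handling and the rule that called a read tagged are not given in the sources used here. Shares were not adjusted for transcript length.

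The tagged table listed 14847 gene IDs and that of all reads listed 22338, of which 1 names no gene and held 1 read of 1 library; it was left out. The supplied table of the TAIR10.1 assembly was used for gene symbols, the biotype and which genes overlap, and its gene lengths were looked at in an exploratory check from which no value is given: 22102 IDs matched, 235 did not (159 of them plastid or mitochondrial) and are given by their ID, and 5746 overlap another listed gene. Reads of overlapping genes and of near-identical gene copies, such as the RBCS and CAB genes, cannot be assigned with certainty, so their single values are uncertain.

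All reads per library ran from 1175516 to 1233999 in enriched poly(A) libraries with ADPRC, from 390009 to 948433 in those without it, and from 378322 to 619122 in unenriched libraries with ADPRC; the unenriched library without ADPRC had 434742, and the total RNA libraries had 6479 with and 1237 without ADPRC. A count of 0 allows up to 3 reads, which is 2.43 to 2.55 TPM, 3.16 to 7.69 TPM, 4.85 to 7.93 TPM, 6.90 TPM, 463 TPM and 2425 TPM in these groups. Intervals of shares are 95% Wilson intervals. Intervals and floors cover counting error only. Where a group had no read of a gene, the fold is a lower bound, computed against a floor of 3 reads over all libraries of that group.

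Tests were made with limma 3.58.1 (lmFit, eBayes with trend, two-sided) in R 4.3.3 on log2(TPM + pseudocount), for genes above 0 in at least 3 libraries of the fit, with only the compared groups in a fit. The pseudocount was the median of the libraries' smallest values above 0: 0.953 TPM for the comparisons with and without ADPRC after enrichment, 1.23 for enriched against unenriched, 1.79 and 0.819 for tagged against all reads in unenriched and enriched libraries, 2.04 for the unenriched control and 0.835 for total against poly(A) RNA. A fold change on this scale understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Tagged and all reads of a library were compared with the library as a block. The lone control library and the lone total RNA library were assumed to vary like the replicated groups. Levels and shares are means ± SD over replicates, and shares per gene were computed for genes at 100 TPM or more. Shares of libraries were compared by exact permutation tests, two-sided, which cannot give a p under 0.1 for 3 against 3.

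The comparisons, the limma tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, per comparison, the 10 genes with the largest fold change in each direction among called genes whose replicates do not overlap between groups and whose higher group is among the more abundant 50% of tested genes; the 10 genes with the most tagged RNA in enriched poly(A) and in total RNA; and the 3 most abundant members of each list. Other genes are named as chosen after their values were seen. The 14 lists were light-harvesting complex genes, photosystem and electron transport genes of the nucleus, Rubisco and Calvin cycle, photorespiration, translation factors, stress and cold response, housekeeping genes (cytoskeleton, ubiquitin and glycolysis), myrosinase cells, root markers, seed storage, nuclear ribosomal RNA, plastid-encoded, mitochondrion-encoded and ribosomal protein genes. The ribosomal protein list was filled by a name rule meant for the cytosolic ribosome and also took in organellar members such as RPL12-A and SSR16. Lists were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry.

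Alternatives covered the pseudocount (1 TPM and 10 times larger), no filter or a mean of 10 TPM, quantile normalization and eBayes without trend. Libraries were also centred on the median of the genes above 0 in every library of the fit. Further alternatives were array weights, all 10 poly(A) libraries in 1 fit, the replicate number as a block and each replicate left out. The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. For the tagged share of genes, edgeR compared tagged with untagged reads relative to the totals of each library. With TMM factors this test made false calls on simulated unenriched libraries; the totals replaced TMM, and likewise the size factors of DESeq2, after results had been seen, and the values with TMM and with these size factors are given as alternatives. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

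The tests were tested on simulated data with 200 genes changed at a dispersion of 0.05. For tagged reads both simulated groups had the tagged level of the enriched libraries with ADPRC, unlike the real control and unenriched libraries. For tagged against all reads, simulated tagged reads in limma had the depth of all reads. The rates of these fits therefore need not hold for the real data. Of 100 genes changed 4-fold, limma recovered 32% for tagged reads with against without ADPRC after enrichment, 65% for all reads in that comparison, 43% and 58% for tagged and all reads enriched against unenriched, and 0% for tagged against all reads in both library types; edgeR recovered 82%, 81%, 67% and 74%, then 1 of 98 genes (1.02%) in unenriched and 70% in enriched libraries. Of genes changed 2-fold, limma recovered 0% to 4% and edgeR 0% to 14%. At most 1 unchanged gene was called in any of these runs.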

Results

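NAD-capped RNA of 12-day-old Arabidopsis seedlings was read in 12 direct RNA libraries, as tagged reads within all reads of each library. Poly(A) RNA enriched for tagged molecules gave 1175516 to 1233999 reads in each of 3 libraries with the tagging enzyme ADPRC. Without the enzyme it gave 390009 to 948433 reads in each of 3 libraries. Unenriched poly(A) RNA gave 378322 to 619122 reads in 3 libraries with ADPRC and 434742 in 1 without it. Enriched total RNA gave 6479 reads with and 1237 without ADPRC. Levels are given in TPM as deposited, which here are CPM of all reads of the library.

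The share of reads that carried the tag was higher with ADPRC and with enrichment. In enriched poly(A) libraries with ADPRC, 19.6% ± 5.00 of reads were tagged (SD, n = 3), with 23.9%, 20.9% and 14.1% in replicates 1, 2 and 3. Without ADPRC the share was 0.192% ± 0.0521 (n = 3), a ratio of 102. Unenriched libraries with ADPRC held 0.625% ± 0.104 tagged reads (n = 3), so that enriched libraries lay 31.4 times above them. The unenriched library without ADPRC held 9 tagged reads, 0.00207% (95% Wilson interval 0.00109% to 0.00393%). The unenriched share with ADPRC lay 302 times above that control and 3.26 times above the enriched control. In total RNA, with 1 library each, 4.80% of reads were tagged with ADPRC (4.31% to 5.35%). Without it 2 reads were tagged, 0.162% (0.0444% to 0.588%). The replicated groups did not overlap (exact permutation test, two-sided, p = 0.1 for each pair, the smallest value that 3 against 3 allows).

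**Figure D1:**
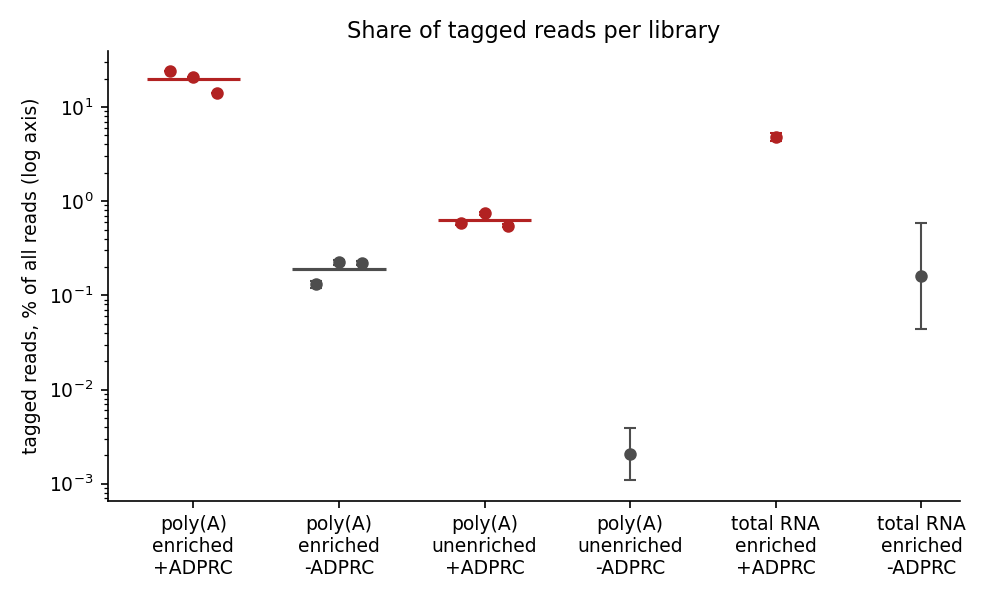
Tagged reads as a percentage of all reads, on a log axis, for each of the 12 libraries by group; points are libraries with 95% Wilson intervals and horizontal lines are group means. Enriched poly(A) libraries with ADPRC lay between 14.1% and 23.9% and those without it between 0.132% and 0.224%, while the unenriched library without ADPRC stood at 0.00207%.

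In enriched libraries with ADPRC 10974 ± 670 genes had a tagged read (SD, n = 3). Without ADPRC it was 706 ± 388 genes (n = 3), and in unenriched libraries with ADPRC 1177 ± 299 (n = 3). The 3 enriched libraries with ADPRC shared 7502 tagged genes, of which 7380 (98.4%) are protein coding, against 98.1% of the 17187 genes with any read in all 3. Of the 7502, 6147 had no tagged read in any poly(A) library without ADPRC. That number rests on low counts. With 10 tagged TPM or more in all 3 libraries with ADPRC and less in each poly(A) library without it, there were 1472 genes. The 3 unenriched libraries with ADPRC shared 326 tagged genes, each of which was also among the 7502. The total RNA library had 193 tagged genes, of which 177 were.

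Which transcripts stood furthest above the background of the tagging reaction was asked in enriched poly(A) RNA with and without ADPRC. RBCS2B (AT5G38420) and RBCS3B (AT5G38410) encode the small subunit of Rubisco, the carbon-fixing enzyme. RBCS2B had 5714 ± 1384 tagged TPM with ADPRC and 7.56 ± 5.36 without it (SD, n = 3 each; log2 fold change 9.54, SE 0.66, limma adjusted p = 5.09e-05). RBCS3B had 15508 ± 4367 and 28.4 ± 9.10 (9.06, SE 0.96, adjusted p = 0.000246). The close copy RBCS1B (AT5G38430) had 961 ± 367 against 1.76 ± 3.04 TPM, and the split of reads between these copies is uncertain. The photosystem I subunit genes PSAL (AT4G12800) and PSAH-1 (AT3G16140, which overlaps AT3G16130) had 1306 ± 363 against 5.19 ± 2.84 and 803 ± 227 against 3.26 ± 3.97 TPM. ECS1 (AT1G31580) had 1436 ± 899 against 3.40 ± 1.62 TPM. The ribosomal protein gene AT3G04840 had 307 ± 23.2 tagged TPM and no tagged read without ADPRC, at least 190-fold higher against the floor of 1.61 TPM. AT5G42530, emb2171 (AT3G04400) and AT4G23670 had 617 ± 359, 663 ± 359 and 1367 ± 456 TPM against 0.351 ± 0.609, 2.05 ± 2.11 and 8.22 ± 8.67.

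On the deposited scale called members of the 11 lists tested were higher with ADPRC. Only the photosystem list had more members higher than lower when libraries were centred on the median of genes tagged in all 6. That centring gives a direction relative to those genes. For genes without a tagged read in the control it rests on the pseudocount. Of the photosystem list 28 of 28 genes were higher, and 12 with 0 lower with that centring. Of the light-harvesting list 20 of 20 were higher, but 0 higher and 6 lower with that centring and 1 and 6 with quantile normalization. Likewise 20 of 20 Rubisco and Calvin cycle genes were higher, but 3 higher and 7 lower with centring. All tested photorespiration (14), stress (17), housekeeping (17), ribosomal protein (45), myrosinase (4) and root genes (4) were higher, but with centring 6, 7, 9, 24, 4 and 4 of them were lower and 0, 1, 1, 2, 0 and 0 higher. Of 17 translation factors 15 were higher, and of 6 mitochondrion-encoded genes 4. Of the 17 and 6 tested, centring called 16 and 6 lower. Quantile normalization called 1 and 2 of them lower with 2 and 0 higher. Without a filter 14 of 15 photorespiration, 17 of 20 stress, 45 of 47 ribosomal protein, 4 of 5 root and 3 of 41 mitochondrion-encoded genes were higher. Adjusted over the list alone the counts were the same, except for 3 of 6 mitochondrion-encoded genes. Photosystem and ribosomal protein genes lay above other genes (camera adjusted p = 0.00310 and 0.0471) and mitochondrion-encoded genes below (0.000425). These calls were lost, with adjusted p = 0.616, 0.616 and 0.448 with an estimated correlation. The fold of a gene without a tagged read in the control rises with its level with ADPRC. Camera did not adjust for this, so the list calls cannot be told apart from abundance.

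Limma called 7384 of 7634 genes higher with ADPRC and 0 lower (7386 genes at unadjusted p under 0.05), and edgeR called 6491 higher and 0 lower. Of the 7634 genes 7502 (98.3%) had a tagged read in all 3 libraries with ADPRC, so the share called depended on the filter, and without it limma called 7324 of 14817 genes higher (49.4%) and 0 lower. Of the 91 genes with a tagged read in all 3 libraries without ADPRC, a set chosen after results had been seen, 90 were higher and 0 lower. The median gene shifted by 2.32 on the log2 scale in limma, by 4.76 in edgeR and by 3.61 in DESeq2. With libraries centred on genes tagged in all 6 libraries it shifted by -3.81, and 54 genes were higher and 7114 lower. Of the 7634 genes 6149 had a tagged read in all 3 libraries with ADPRC and none in those without it. With centring the direction of such genes rests on the pseudocount, so centring cannot decide it. The count of called genes was 4408 with DESeq2 and 1215 for genes at a mean of 10 TPM, and quantile normalization gave 1535 higher and 1466 lower. Array weights ended the calls of the named genes except AT3G04840, quantile normalization those of RBCS1B, PSAH-1, PSAL, emb2171 and AT4G23670, and centring that of AT4G23670.

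Unenriched poly(A) RNA put the same question without selection of tagged molecules, against 1 control library. RBCS3B had 409 ± 76.1 tagged TPM with ADPRC (SD, n = 3) and no tagged read in the control, at least 59.3-fold higher against its floor of 6.90 TPM. RBCS1A (AT1G67090) and RBCS2B had 174 ± 51.9 and 151 ± 21.3 TPM and no control read, at least 25.2-fold and 22.0-fold higher. The photosystem II subunit genes PSBX (AT2G06520) and PSBR (AT1G79040, which overlaps AT1G79050) had 121 ± 14.0 and 92.5 ± 38.3 TPM, at least 17.6-fold and 13.4-fold higher. PSBW (AT2G30570), of the same photosystem, had 146 ± 9.37 TPM and 1 tagged read, 2.30 TPM, in the control (log2 fold change 5.08, SE 0.35). AT2G45180, DRT112 (AT1G20340, plastocyanin), PSAO (AT1G08380, photosystem I) and FED A (AT1G60950, ferredoxin) had 118 ± 51.9, 77.9 ± 8.76, 75.4 ± 17.7 and 67.4 ± 8.06 TPM. Without a control read, these were at least 17.1, 11.3, 10.9 and 9.77-fold higher.

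The filter kept the 326 genes tagged in all 3 unenriched libraries with ADPRC, so that a level above the control, with 9 tagged reads in all, was set before the test. No direction is therefore given for the lists. Of these genes 27 belong to the photosystem, 17 to the light-harvesting, 14 to the ribosomal protein, 10 to the Rubisco and Calvin cycle, 7 to the stress, 5 to the photorespiration, 4 to the housekeeping and 2 to the translation factor list. Limma called 324 of the 326 higher and 0 lower (324 at unadjusted p under 0.05), edgeR 99 and DESeq2 62. Without a filter limma called 112 of 2372 genes higher and 0 lower. The count rests on values near 1 read and was 118 with the larger pseudocount, 63 at a mean of 10 TPM and 21 with centring. It was 202, 210 and 147 without replicates 1, 2 and 3 of the libraries with ADPRC. The median gene shifted by 1.67 in limma, 4.24 in edgeR and 3.44 in DESeq2, and by -0.26 with centring. Quantile normalization called 46 genes higher and 39 lower and turned PSBW to a log2 fold change of -0.05.

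Tagged RNA with and without enrichment was compared in libraries with ADPRC. GSTF8 (AT2G47730), a glutathione S-transferase gene, had 145 ± 40.9 tagged TPM after enrichment and no tagged read without it (SD, n = 3 each), at least 75.1-fold higher against a floor of 1.93 TPM. AT1G54410, ATG8C (AT1G62040, of autophagy) and EXPA1 (AT1G69530, a cell wall expansin) had 73.2 ± 25.4, 70.1 ± 7.51 and 69.3 ± 14.6 TPM and none without enrichment. They were at least 38.0, 36.4 and 36.0-fold higher. AT2G27385 rose from 3.34 ± 3.24 to 327 ± 110 TPM (log2 fold change 6.47, SE 0.73, limma adjusted p = 0.000426). The ribosomal protein gene AT1G48830 rose from 1.48 to 191 TPM and the aquaporin gene PIP1A (AT3G61430) from 1.08 ± 1.87 to 120 ± 40.3. AT2G29290, AT4G05070 and AT5G21020 rose to 121 ± 17.1, 156 ± 46.5 and 142 ± 24.2 TPM from 1.08, 1.73 and 1.42.

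All 28 photosystem genes had more tagged RNA after enrichment. With libraries centred on the median of genes tagged in every library compared, 9 were higher and 0 lower. Quantile normalization gave 0 higher and 1 lower. All 20 light-harvesting genes also had more tagged RNA, but 3 were higher and 2 lower with that centring. So had all 20 Rubisco and Calvin cycle genes, with 5 and 3. All tested ribosomal protein (45), translation factor (17), stress (17), housekeeping (17), photorespiration (14), myrosinase (4) and root genes (4) were higher. But with that centring 9, 7, 3, 2, 2, 3 and 3 of them were lower and 2, 0, 1, 3, 1, 0 and 0 higher. Of 7 mitochondrion-encoded genes 4 were higher, but 7 were lower with that centring. Without a filter 45 of 47 ribosomal protein, 16 of 17 translation factor, 17 of 20 stress, 14 of 15 photorespiration, 4 of 5 root and 4 of 41 mitochondrion-encoded genes were higher. Adjusted over the list alone the counts were the same. Light-harvesting and photosystem genes lay above other genes (camera adjusted p = 8.92e-06 and 1.85e-06), a call lost at adjusted p = 0.479 for both with an estimated correlation. So were the calls of Calvin cycle, ribosomal protein and housekeeping genes above others (0.0162, 0.0162 and 0.0334) and of mitochondrion-encoded genes below (0.00120). The fold of a gene without a tagged read before enrichment rises with its level after it. Camera did not adjust for this, so these calls cannot separate enrichment from abundance.

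Limma called 7297 of 7623 genes higher after enrichment and 0 lower (7303 at unadjusted p under 0.05), and edgeR 5103 higher and 0 lower. Of the 7623 genes 7502 (98.4%) had a tagged read in all 3 enriched libraries, and without the filter limma called 7221 of 14752 genes higher (48.9%) and 0 lower. Of the 326 genes tagged in all 3 unenriched libraries, a set chosen after results had been seen, 325 were higher and 0 lower. The median gene shifted by 2.01 in limma, 4.33 in edgeR and 3.32 in DESeq2. With centring it shifted by -2.31, and 59 genes were called higher and 6063 lower. Of the 7623 genes 5342 had a tagged read in all 3 enriched libraries and none in the unenriched ones. With centring the direction of such genes rests on the pseudocount, so centring cannot decide it. The count of called genes was 3951 with DESeq2 and 1237 at a mean of 10 TPM, and quantile normalization gave 667 higher and 1071 lower. Array weights ended the calls of the 10 genes named. Quantile normalization ended those of AT2G27385, AT1G48830, AT2G29290, PIP1A, AT4G05070 and AT5G21020.

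The part of a gene's reads that carried the tag was measured as tagged over all reads of the gene. Whether untagged reads covered whole transcripts was not tested, so the share describes reads and not transcripts. In unenriched libraries RBCS3B had the highest share among genes with at least 1000 reads, 2.83% ± 0.487 (SD, n = 3), and 45.9% ± 6.78 after enrichment. AT4G23670 followed with 2.50% ± 0.529 and 36.0% ± 6.46. PSBW had 2.09% ± 0.127 and 43.4% ± 7.56, RBCS2B 2.02% ± 0.209 and 43.0% ± 5.15, and ECS1 2.08% ± 0.533 and 45.3% ± 6.55. The ubiquitin fusion gene UBQ1 had 2.12% ± 1.16 and 44.0% ± 12.1, and the photosystem I gene PSAD-2 2.14% ± 0.372 and 36.7% ± 10.8. The light-harvesting genes CAB1 (AT1G29930) and LHB1B2 (AT2G34420, which overlaps AT2G08665) had low shares, 0.206% ± 0.0342 and 0.151% ± 0.0191 before and 7.50% ± 1.45 and 7.26% ± 2.01 after enrichment. RCA (AT2G39730, Rubisco activase) had 0.128% ± 0.0172 and 8.56% ± 2.53, and the beta-glucosidase gene PYK10 (AT3G09260) 0.0932% ± 0.0333 and 7.31% ± 1.85. No tagged read was found before enrichment for the chaperone gene HSC70-1 (AT5G02500) among 2095 reads (95% Wilson upper limit 0.183%). Nor was one found for GLDP1 (AT4G33010, glycine decarboxylase) among 1619 (0.237%), for the elongation factor gene AT5G60390 among 1289 (0.297%) or for PGK1 (AT3G12780, phosphoglycerate kinase) among 1058 (0.362%). After enrichment these 4 genes had 2.66% ± 0.852, 0.966% ± 0.273, 3.67% ± 1.29 and 5.48% ± 1.78. UBQ1, PSAD-2 and PGK1 were chosen after their values were seen.

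**Figure D2:**
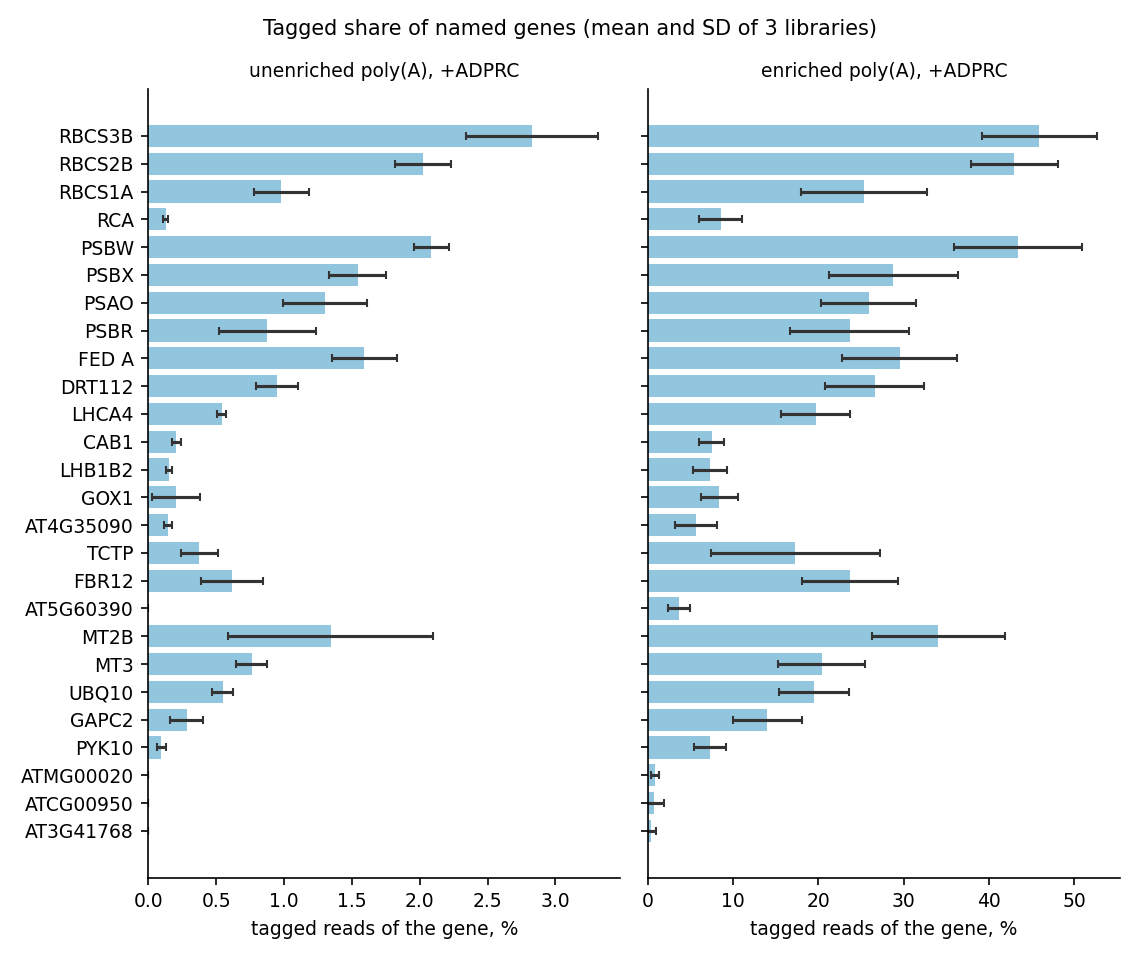
Tagged reads as a percentage of all reads of a gene, for 26 genes in unenriched and in enriched poly(A) libraries with ADPRC; bars are means with SD over 3 libraries. RBCS3B stands at 2.83% and 45.9% and RCA at 0.128% and 8.56% before and after enrichment.

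Over the 1328 genes at 100 TPM or more the median share was 0.467% in unenriched libraries, with 0 tagged reads for 376 genes and over 2% for 69. These 2 counts depend on depth. Among the 237 genes at 500 TPM or more 18 had 0 tagged reads and 10 had over 2%. A count of 0 therefore need not mean a gene without tagged RNA. After enrichment it was 18.5% over 1391 genes (quartiles 11.7% and 25.5%), over 50% for 9 genes and 0 for 4. In enriched libraries without ADPRC the median was 0.132% over 1370 genes. Shares before and after enrichment were ranked alike across 176 genes with 1000 or more unenriched reads (Spearman rho 0.847, Pearson r of log2 shares 0.802; genes are not independent replicates). By edgeR with library totals, 0 of 7623 genes were called for a change of share under enrichment relative to that of the library (239 at unadjusted p under 0.05; limma and DESeq2 were not run on this contrast). With TMM, the scaling first used and given up after its results had been seen, edgeR called 97 genes, each higher (517 at unadjusted p under 0.05), so this result depended on the scaling.

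The pooled share of the lists is given as measured, and differences between lists were not tested. Longer genes had lower tagged shares in an exploratory check with the lengths of the supplied gene table, whose build need not be that of the authors, and the shares of genes and lists are not adjusted for this. Rubisco and Calvin cycle genes had 1.21% ± 0.175 tagged reads before and 32.1% ± 6.47 after enrichment (SD, n = 3 each). RBCS3B gave 654 of the 1307 and 56057 of the 109719 tagged reads of this list. Without the 4 RBCS genes, a subset chosen after values were seen, the other 16 members had 0.224% ± 0.0590 and 9.73% ± 2.59. Photosystem genes had 1.03% ± 0.139 and 26.0% ± 5.92, stress genes 1.02% ± 0.358 and 26.0% ± 5.97, and ribosomal protein genes 0.761% ± 0.211 and 25.5% ± 7.21. Housekeeping genes had 0.360% ± 0.0831 and 17.9% ± 4.97, and light-harvesting genes 0.349% ± 0.0399 and 14.0% ± 2.68. Translation factors had 0.303% ± 0.0722 and 15.2% ± 6.89, and photorespiration genes 0.232% ± 0.0409 and 10.5% ± 2.72. Root markers had 0.0908% ± 0.0316 and 7.38% ± 1.86, and myrosinase genes 0.0672% ± 0.116 and 5.13% ± 1.68. Mitochondrion-encoded genes had 0.173% ± 0.162 (2 of 1432 reads) and 7.67% ± 4.10 (130 of 1627). No tagged read was found in unenriched libraries among 2628 reads of ribosomal RNA genes, 709 of plastid-encoded genes or 15 of seed storage genes. After enrichment there were 1 of 523, 2 of 649 and 3 of 14. In enriched libraries without ADPRC the shares were 0.145% to 0.512% for lists with a tagged read.

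**Figure D3:**
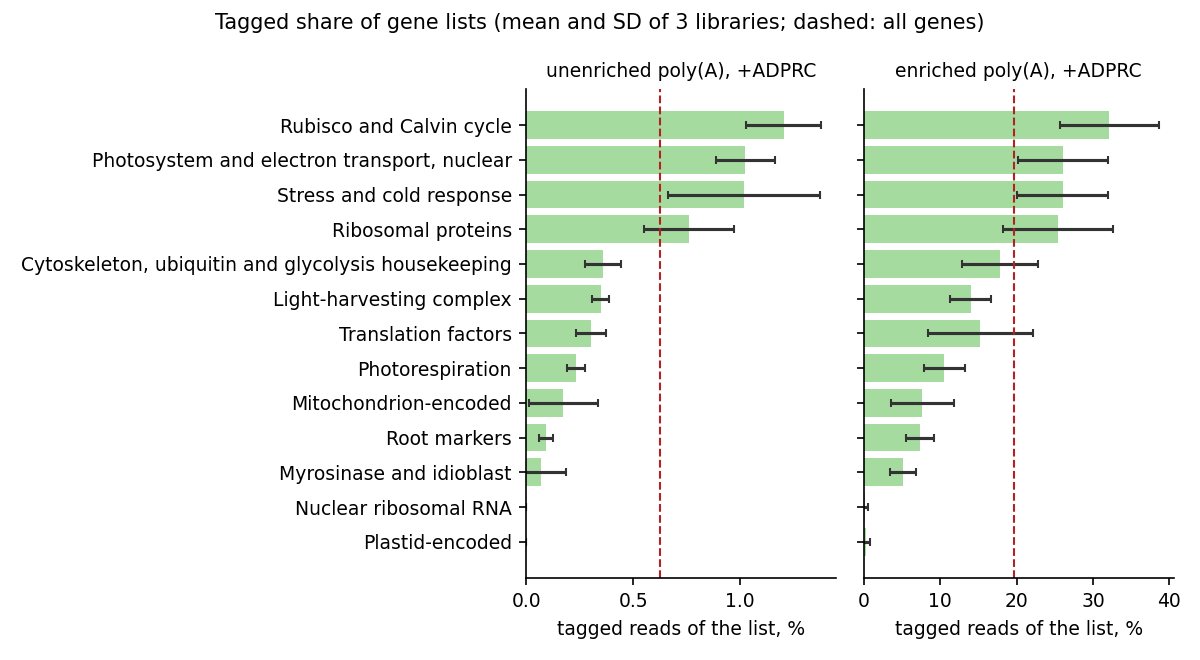
Pooled tagged share of 13 gene lists in unenriched and enriched poly(A) libraries with ADPRC; bars are means with SD over 3 libraries, and the dashed line is the mean share of all genes (0.625% and 19.6%). Rubisco and Calvin cycle genes stand at 1.21% and 32.1%, but at 0.224% and 9.73% without the 4 RBCS genes, and photorespiration genes at 0.232% and 10.5%, shares computed within each library, for which no other scaling was run.

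Tested against all reads of the same libraries, limma called 13506 of 13519 genes lower in unenriched and 17088 of 17900 lower in enriched libraries. It called 0 higher (13506 and 17104 at unadjusted p under 0.05), a direction fixed because tagged reads are part of all reads. Before enrichment the largest difference was that of the light-harvesting gene CAB3 (AT1G29910), with 8.00 ± 2.61 of 9607 ± 550 TPM tagged (log2 fold change -9.97, SE 0.39, adjusted p = 1.04e-09). RCA had 14.0 ± 1.93 of 10938 ± 83.5 TPM tagged, PYK10 2.61 ± 0.980 of 2786 ± 303, and the aminotransferase gene AT1G23310 3.24 ± 4.16 of 1970 ± 51.3. LHB1B2 and the overlapping AT2G08665 had 18.7 ± 2.65 of 12390 ± 287 and 19.5 ± 1.64 of 12540 ± 369. HSC70-1, GLDP1 and the ribosomal RNA genes AT3G41768 and ENSRNA049451242-T1 had 0 of 1339 ± 124, 1042 ± 84.3, 1106 ± 116 and 1101 ± 125 TPM. After enrichment the largest were those of AT5G53140 (0.270 ± 0.468 of 820 ± 76.0 TPM), GUN5 (AT5G13630, of chlorophyll synthesis; 0.543 ± 0.470 of 466 ± 107) and AT2G43150 (0 of 281 ± 123). CLPC1 (AT5G50920, a chloroplast chaperone) had 1.91 ± 1.86 of 470 ± 80.3 and ATMS1 (AT5G17920, methionine synthase) 1.65 ± 0.807 of 427 ± 119. GLU1 (AT5G04140, glutamate synthase, which overlaps AT5G04150) had 0.816 ± 0.819 of 262 ± 49.6 and HA2 (AT4G30190, a proton pump) 0.554 ± 0.480 of 188 ± 30.3. AT2G24060, LOS1 (AT1G56070, a translation elongation factor) and ENSRNA049451242-T1 had 4.66 ± 2.47 of 714 ± 110, 0.827 ± 0.0212 of 229 ± 49.8 and 0 of 106 ± 20.4.

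Relative to the share of the whole library, edgeR on tagged against untagged reads, scaled by library totals, called 26 genes higher and 20 lower of 13519 in unenriched libraries. RBCS3B was higher by 2.22 on the log2 scale, PSBW by 1.76, RBCS2B by 1.73 and ECS1 by 1.68 (edgeR adjusted p = 1.61e-209, 7.81e-49, 7.77e-50 and 5.75e-07). CAB3, RCA and LHB1B2 were at -3.01, -2.30 and -2.07. With totals DESeq2 placed RBCS3B, PSBW, RBCS2B and ECS1 at 2.21, 1.77, 1.72 and 1.72. The DESeq2 adjusted p was larger for each, at 6.26e-08, 0.000250, 0.000359 and 0.00945. The totals replaced TMM and the size factors of DESeq2 after results had been seen. With TMM RBCS3B was at 0.35 and called, while PSBW, RBCS2B and ECS1, at -0.09, -0.13 and -0.15, were not. With its own size factors DESeq2 placed these 4 genes at -0.98, -1.42, -1.46 and -1.46 and called the last 3 lower. CAB3, RCA and LHB1B2 were lower with each of these scalings. DESeq2 with totals ended the calls of GLDP1 and AT1G23310 against all reads, and quantile normalization that of AT1G23310. Of the photosystem list 10 genes were higher and 1 lower (16 and 1 adjusted over the list alone), 11 and 1 with quantile normalization, but 0 and 6 with median centring, 0 and 21 with TMM and 0 and 28 with the size factors of DESeq2. Of the light-harvesting list 0 were higher and 8 lower (0 and 10), with more lower than higher under each scaling. Photorespiration genes were lower in 3 (7), with 0 called by DESeq2. Rubisco and Calvin cycle genes were higher in 3 and lower in 2 (5 and 8), with 2 and 12 under centring and 2 and 7 under quantile normalization. Stress genes were higher in 2 (2 higher and 1 lower), with 13 and 3 under centring and 2 and 3 under quantile normalization, and ribosomal protein genes higher in 1 (3), with 1 higher and 5 lower under quantile normalization. A root marker was lower (1), with 3 higher and 1 lower under centring, and a ribosomal RNA gene was lower (2). Under centring, list members without a tagged read take a direction that rests on the pseudocount. TMM and the size factors of DESeq2 called Calvin cycle genes lower in 14 and 18 (1 and 0 higher), stress genes in 5 and 6 and ribosomal protein genes in 9 and 30 (0 higher). Of the other lists edgeR called 0 with totals, and over the list alone 3 translation factors and 1 myrosinase gene were lower. With TMM 10 translation factors, 7 housekeeping genes, 1 myrosinase and 1 mitochondrion-encoded gene were lower, and with the size factors of DESeq2 14, 17, 3 and 3, and 2 plastid-encoded genes.

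Enriched libraries gave 771 genes with a higher and 3674 with a lower share of 17900 by edgeR. RBCS3B was at 1.83, PSBW at 1.68, RBCS2B at 1.66, RCA at -1.40, GLDP1 at -4.56 and LOS1 at -5.96. Of the photosystem list 19 genes were higher and 4 lower (19 and 4 adjusted over the list alone), and of the ribosomal proteins 14 and 7 (18 and 7). Light-harvesting genes were higher in 3 and lower in 11 (4 and 13), and 5 and 5 with median centring. Calvin cycle genes were higher in 4 and lower in 12 (4 and 12), photorespiration genes in 2 and 11 (2 and 11), and translation factors in 1 and 12 (2 and 13). Housekeeping genes were higher in 2 and lower in 10 (3 and 10), stress genes in 7 and 5 (7 and 6), and mitochondrion-encoded genes in 1 and 3 (1 and 3), which centring turned to 29 and 3 and quantile normalization to 25 and 3. With 0 higher, 3 myrosinase, 3 root, 2 plastid-encoded and 2 ribosomal RNA genes were lower, the same over the list alone, and with centring 3 plastid-encoded and 2 root genes were higher. No seed storage gene was called (0 of 2), and 2 were higher with centring or quantile normalization. TMM and the size factors of DESeq2 turned none of these lists.

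The direction of these relative calls depended on the scaling. In unenriched libraries DESeq2 gave 65 higher and 9 lower with totals and 1 and 1901 with its own size factors, edgeR with TMM 2 and 275, median centring 12346 and 295 and quantile normalization 2365 and 2608. Only 2370 genes had a tagged read in at least 1 of these libraries, so most of the 12346 had none. Their direction with centring rests on the pseudocount and says nothing of their share. In enriched libraries DESeq2 gave 438 and 1604 with totals and 620 and 1278 with its own size factors, TMM 946 and 3277, median centring 4424 higher and 2182 lower and quantile normalization 3143 and 2365. The median gene of the unenriched libraries was at -3.04 in limma, 3.21 with centring, -4.27 in edgeR, -4.31 with TMM, 2.23 in DESeq2 and -0.94 with its own size factors. That of the enriched libraries was at -2.30 in limma, 0.30 with centring, -0.88 in edgeR, -0.78 with TMM and -0.72 with the size factors of DESeq2. For genes at a mean of 10 TPM limma called 5294 lower before and 6011 lower after enrichment.

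Among all reads of enriched libraries, tagged or not, 22 genes differed between reactions with and without ADPRC. ATG8C had 123 ± 17.1 TPM with and 30.2 ± 11.3 without ADPRC (SD, n = 3 each; log2 fold change 2.05, SE 0.27, limma adjusted p = 0.0139). The RNA-binding protein gene RBP45A had 83.3 against 23.0 TPM and AT5G22580 601 ± 198 against 175 ± 42.1. The ribosomal protein gene AT3G04840 had 689 ± 46.5 against 240 ± 66.6 TPM (1.55, SE 0.19, adjusted p = 0.0123), AT4G14320 425 ± 68.5 against 153 ± 41.7 and AT1G48830 383 against 126. RPL24A (AT2G36620, which overlaps AT2G36610) had 256 ± 21.2 against 97.3 ± 28.7 and AT4G13170 (which overlaps AT4G13160) 112 ± 9.21 against 38.8 ± 7.40. AT4G02450 (which overlaps AT4G02440) and GRP5 (AT3G20470) had 163 ± 18.9 against 58.6 ± 9.25 and 162 ± 34.7 against 60.9 ± 16.2 TPM.

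Lower with ADPRC was AT5G53140, of a protein phosphatase family, with 820 ± 76.0 against 2498 ± 413 TPM (log2 fold change -1.60, SE 0.16, limma adjusted p = 0.00280). AT2G24060, of a translation initiation factor family, had 714 ± 110 against 2131 ± 693 TPM, and its overlapping neighbour QWRF4 (AT2G24070) 14.1 ± 2.96 against 62.2 ± 22.8. MED21 (AT4G04780), a Mediator subunit gene, had 46.0 ± 17.8 against 146 ± 13.1 TPM. MIND (AT5G24020), of chloroplast division, had 93.2 ± 35.4 against 271 ± 6.06, and RHON1 (AT1G06190), of chloroplast RNA processing, 58.4 ± 4.08 against 123 ± 2.25. PDE345 (AT2G01140, which overlaps AT2G01130) and AT2G32090 (which overlaps AT2G32080) had 178 ± 28.1 against 416 ± 36.6 and 93.8 ± 8.65 against 201 ± 16.6 TPM.

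Limma called 14 of these genes higher and 8 lower of 19150 tested (1422 at unadjusted p under 0.05). The groups did not overlap for 13.5% of genes, against 10% by chance for 3 against 3. Of the lists, 2 of 47 ribosomal protein genes were higher (3 adjusted over the list alone; camera adjusted p = 0.402, and adjusted p = 0.905 with an estimated correlation), and 0 members of the other lists were called. Adjusted over the list alone, 2 Calvin cycle genes and 1 stress gene were higher, and 1 light-harvesting, 1 root and 1 mitochondrion-encoded gene were lower. The light-harvesting list lay below other genes (camera adjusted p = 0.00654, and adjusted p = 0.665 with an estimated correlation). No gene was called without replicate 1, 2 or 3 of the libraries with ADPRC, without replicate 3 of those without it, or without the trend in eBayes. Without replicates 1 and 2 of the libraries lacking ADPRC 13 and 2 were called, AT5G53140 among them each time. Leaving out that replicate 1 ended the calls of RBP45A, AT5G22580, RPL24A, MED21, MIND, PDE345, AT2G32090 and RHON1, and replicate 2 those of the named genes other than AT5G53140. Other settings gave more, with 96 by edgeR, 58 by DESeq2, 51 with quantile normalization, 50 with array weights, 60 at a mean of 10 TPM, 35 with the larger pseudocount and 34 without a filter. A block by replicate number gave more still, as given with the processing settings below. With all 10 poly(A) libraries 38 were called, without QWRF4 and RHON1, and median centring ended the call of RHON1.

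Enrichment changed the makeup of all reads in libraries with ADPRC. AT2G24060 and AT5G53140 stood out among abundant genes. They had 714 ± 110 and 820 ± 76.0 TPM after enrichment against 26.6 ± 7.76 and 56.6 ± 8.88 without it (SD, n = 3 each; log2 fold changes 4.71, SE 0.21, limma adjusted p = 3.30e-07, and 3.83, SE 0.16, adjusted p = 3.07e-07). Small-subunit ribosomal RNA was lower after enrichment, with 97.3 ± 14.7 against 1106 ± 116 TPM for AT3G41768 and 45.3 ± 5.58 against 593 ± 97.1 for AT2G01010 (-3.50 and -3.67). The U3 small nucleolar RNA gene U3D (AT5G54075) had 0.567 ± 0.982 against 80.9 ± 12.4 TPM. U3B (AT5G53902) had no read against 14.4 ± 1.47 TPM, at least 17.4-fold lower against a floor of 0.826 TPM. AT5G06845 fell from 93.1 ± 16.5 to 2.26 ± 3.23 TPM. ENSRNA049493776-T1, ENSRNA049493783-T1, ENSRNA049493835-T1 and ENSRNA049495688-T1, which have no name in the table used, fell from 50.9 ± 9.08, 30.3 ± 10.9, 29.8 ± 12.8 and 26.6 ± 2.14 TPM to 0.554 to 1.11. ENSRNA049493778-T1 had 13.3 ± 3.21 TPM before and none after, at least 16.1-fold lower. Among low genes QWRF4 reached 14.1 ± 2.96 TPM from 0.596 ± 1.03. FP3 (AT5G63530) and AT2G01755 (which overlaps AT2G01750) reached 14.2 ± 8.47 and 10.7 ± 4.03 from 0, at least 7.36 and 5.57-fold higher. AT2G31150, rps15ab (AT2G19720), ORS1 (AT2G41230), AT3G27210 and AT4G34790 reached 10.5 to 17.6 TPM from 0.538 to 2.15.

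**Figure D4:**
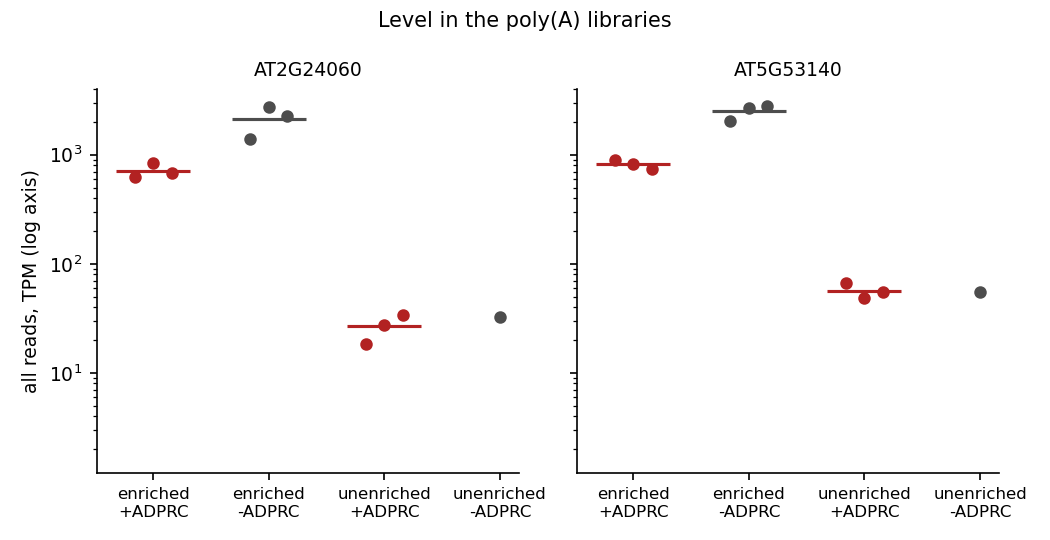
All reads of AT2G24060 and AT5G53140 in TPM on a log axis, in each of the 10 poly(A) libraries by group; points are libraries and bars are group means. Enriched libraries without ADPRC averaged 2131 and 2498 TPM, enriched libraries with ADPRC 714 and 820, and unenriched libraries with ADPRC 26.6 and 56.6.

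Of 20 stress and cold response genes 8 rose with enrichment and 0 fell (11 and 1 adjusted over the list alone), with 8 or more higher under every scaling, where DESeq2 alone called 1 lower. The camera call of this list was lost, with adjusted p = 0.108 with an estimated correlation. The RNA-binding protein gene GRP7 rose from 36.9 ± 13.3 to 193 ± 76.7 TPM (SD, n = 3 each; log2 fold change 2.32, limma adjusted p = 0.00208). The dehydrin gene COR47 rose from 73.5 ± 3.54 to 215 ± 53.0 TPM and the membrane protein gene RCI2A from 226 ± 38.4 to 540 ± 73.7. Of 15 photorespiration genes 6 fell and 0 rose (8 and 0), with 5 to 7 lower and 0 higher under every scaling. The call of the list was lost, with adjusted p = 0.125 with an estimated correlation. The glycolate oxidase gene GOX1 fell from 1894 ± 61.0 to 1011 ± 33.7 TPM and the catalase gene AT4G35090 from 2190 ± 181 to 1100 ± 172. Of 17 translation factors 6 fell and 0 rose (8 and 0), with 5 or 6 lower under every scaling, among them TCTP (7853 ± 582 to 3740 ± 1775 TPM) and AT5G19510 (446 ± 30.4 to 190 ± 34.1). This list too had adjusted p = 0.125 with an estimated correlation. Of 20 light-harvesting genes 1 was higher and 5 lower (2 and 10), with more lower than higher under every scaling, and adjusted p = 0.165 with an estimated correlation. CAB1 fell from 24424 ± 976 to 14682 ± 693 TPM and LHB1B2 from 12390 ± 287 to 4806 ± 175. These examples from the lists were chosen after their values were seen, as were those of the next lists. Without ADPRC, against 1 unenriched library, median log2 folds of the stress, photorespiration, translation factor and light-harvesting lists were 0.82, -0.29, -0.17 and -0.20. With ADPRC they were 1.11, -0.32, -0.40 and -0.31 in the same fit of all 10 poly(A) libraries. The photosystem, housekeeping, root and plastid-encoded medians differed in sign with and without ADPRC. This comparison was chosen after the data had been seen.

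Members of the other photosynthesis lists moved both ways. Of 28 photosystem genes 6 were higher and 1 lower (10 and 3 adjusted over the list alone). PSAH-1 rose from 1383 ± 3.15 to 2511 ± 354 TPM and PSAN fell from 5955 ± 79.1 to 3051 ± 511. Of 20 Rubisco and Calvin cycle genes 3 were higher and 4 lower (6 and 6), with 5 and 4 under quantile normalization. RBCS3B rose from 14472 ± 797 to 33291 ± 4825 TPM and RBCS2B from 7473 ± 640 to 13178 ± 1764, and the aldolase gene FBA2 fell from 3749 ± 139 to 2000 ± 390. Of 47 ribosomal protein genes 5 were higher and 8 lower (8 and 12), with a median of 0.11, while camera put the list below other genes without calling it (adjusted p = 0.294). Called members were lower for ribosomal RNA (2 of 4; 2 over the list alone), plastid-encoded (4 of 24; 6) and mitochondrion-encoded genes (4 of 55; 4). Of 17 housekeeping genes 3 were lower (2 higher and 5 lower over the list alone), with 1 higher under quantile normalization and edgeR. Of the myrosinase and root genes 1 of 4 and 1 of 5 were lower (1 and 1), with medians of 0.19 and 0.32, and 0 of 3 seed storage genes were called (1 lower).

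Camera placed the stress list above other genes (adjusted p = 5.27e-07) and the light-harvesting, photorespiration, translation factor, ribosomal RNA, mitochondrion-encoded, plastid-encoded, housekeeping and seed storage lists below. These calls were lost, with adjusted p = 0.108, 0.165, 0.125, 0.125, 0.0797, 0.126, 0.125, 0.125 and 0.195 with an estimated correlation. Limma called 563 genes higher and 369 lower of 18831 (3861 at unadjusted p under 0.05), but DESeq2 370 higher and 445 lower, and without enriched replicates 2 and 3 limma gave 76 and 75, and 102 and 111. The groups did not overlap for 24.8% of genes, against 10% by chance. The median gene shifted by 0.20, by 0.13 with centring and by -0.01 with quantile normalization. Without replicates 1, 2 and 3 of the enriched libraries 389, 151 and 213 genes were called, and 496, 392 and 391 without those of the unenriched ones. The count was 37 without the trend, 1453 with edgeR and 1469 at a mean of 10 TPM.

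Without the trend the calls of the list members named above ended, as did those of the genes under 20 TPM that rose, except AT2G01755. DESeq2 ended those of TCTP, U3B, ENSRNA049493778-T1, ENSRNA049495688-T1 and the genes under 20 TPM that rose, AT2G01755 included. Centring ended those of RBCS3B, RBCS2B and CAB1. Single left-out libraries ended those of GRP7 (enriched 3), FBA2 (enriched 2 or 3), RBCS2B (enriched 3 or unenriched 2), CAB1 (enriched 2 or 3, unenriched 2 or 3), TCTP (any but enriched 1) and the genes under 20 TPM that rose (FP3 without enriched 2 or 3, the others without any enriched library, AT2G01755 in no case). Leaving out unenriched replicates 1, 2 and 3 with ADPRC ended 2, 4 and 5 calls of named genes, not all of them listed here. AT2G24060, AT5G53140, AT3G41768, AT2G01010, U3D and AT5G06845 stayed called in every setting run.

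The same enrichment without ADPRC, 3 libraries against the 1 unenriched control, was compared across genes. Over 1361 genes at 100 TPM or more, log2 folds with and without ADPRC correlated (Pearson r 0.796, Spearman rho 0.752; genes are not independent replicates, and the comparisons share no library). The r was 0.515 over 8684 genes at 10 TPM or more and 0.313 over all 19871. Of the 563 genes higher with ADPRC 494 (87.7%) had the same sign without it, and of the 369 lower ones 346 (93.8%). Over the 19871 genes the sign was the same for 62.4%, and for 78.5% at 100 TPM or more. This relation was chosen after the data had been seen.

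**Figure D5:**
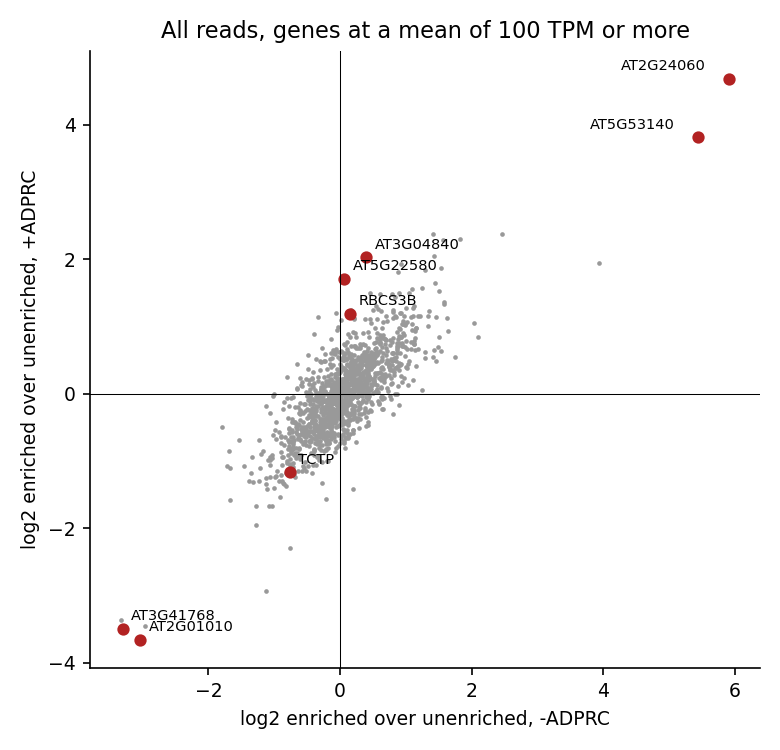
Log2 fold of all reads, enriched over unenriched, for 1361 genes at 100 TPM or more, with ADPRC on one axis and without on the other; each point is a gene. The folds correlate at r 0.796, and AT2G24060 and AT5G53140 lie far from the rest in both.

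Total RNA, which was not selected for poly(A) tails, was read once with ADPRC, and few reads limit each value. RBCS3B had 38 tagged of 134 reads, 28.4% (95% Wilson interval 21.4% to 36.5%), and RBCS2B 13 of 40, 32.5% (20.1% to 48.0%). ECS1 had 13 of 27, 48.1% (30.7% to 66.0%), and PSBW 11 of 54, 20.4% (11.8% to 32.9%). RBCS1A had 8 of 140, 5.71% (2.92% to 10.9%), DRT112 5 of 61, PSBR 5 of 49, PSAO 4 of 41, TCTP 4 of 34 and CAB1 3 of 113. Without ADPRC CAB1 had 1 tagged read of 21 and the others 0. Plastid-encoded genes made up 13.5% of the total RNA reads with ADPRC (876 of 6479), with 2 tagged reads, and 16.2% without it. In the replicated poly(A) groups they made up 0.0179% to 0.0443%.

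Against enriched poly(A) RNA with ADPRC, the genes named by the largest downward folds had no tagged read in the 1 total RNA library. PSAG (AT1G55670, which overlaps AT1G55673) had no tagged read in total RNA and 2059 ± 807 TPM in poly(A) RNA (SD, n = 3), at least 4.45-fold lower against a floor of 463 TPM. Also without a tagged read, FED A, PSAE-1 (AT4G28750, which overlaps AT4G28740), LHCB2.1 (AT2G05100) and LHCA1 (AT3G54890) were at least 4.16, 2.51, 2.29 and 1.97-fold lower. PSAF (AT1G31330), PSAH-1, LHCB5 (AT4G10340), PSBTN (AT3G21055) and RCA were at least 1.43 to 1.76-fold lower. These folds are not adjusted for the whole library, where 4.80% of reads were tagged against 19.6% in poly(A) RNA. The genes with the largest folds upward each rest on 1 tagged read, 154 TPM, below that floor, so no fold is given. They were the transcription factor genes WRKY28 (AT4G18170) and WRKY45 (AT3G01970), PYR4, GPX3, BGAL1, RALFL31, AT2G07644, AT3G23880, AT2G07671 and AT2G39440.

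Limma called 84 genes higher and 6774 lower of 7508 in total RNA (6952 at unadjusted p under 0.05), but edgeR and DESeq2 called 0, the named ones included. A count of 0 in that library allows up to 463 TPM, so a lower call of a gene under that level in poly(A) RNA rests on depth. No direction is given for the lists, of which edgeR called 0 members. Quantile normalization gave 411 genes higher and 877 lower. The median gene was at -2.48, and at 0.05 with quantile normalization. The limma count was 1608 with the larger pseudocount, 4522 without a filter, 1625 at a mean of 10 TPM and 4538 without replicate 1 of the poly(A) libraries.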

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

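All tests in this part were chosen only after results had been seen. The effect of enrichment on all reads was compared between libraries with and without ADPRC, and 3 genes differed. The ribosomal protein gene AT3G04840 rose by 2.00 on the log2 scale with ADPRC and was at 0.38 without it, a difference of 1.61 (edgeR interaction, adjusted p = 0.0433). AT5G22580 was at 1.79 and 0.01, a difference of 1.78 (adjusted p = 0.00934), and AT3G06355 at -2.88 and -1.09, a difference of -1.80 (adjusted p = 0.00934). EdgeR called 3 of 19871 genes (906 at unadjusted p under 0.05) and limma 0 (1393 at unadjusted p under 0.05). The arm without ADPRC rests on 1 unenriched library.

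Tagged reads were also found in the enriched libraries without ADPRC, 513, 1166 and 2082 in replicates 1, 2 and 3. Their genes resembled all reads of the same libraries more than tagged reads with ADPRC: fitted as a mixture of both, 0.114, 0.0598 and 0.0121 of them followed the latter (upper 95% bootstrap limits 0.214, 0.134 and 0.0578). This argues against carryover from the libraries with ADPRC as the main source. Tag calls made in error on untagged reads stay open: the enriched share was 92.6 times that of the unenriched control, but that is 1 library with 9 tagged of 434742 reads, and the rate of such errors was not measured in either kind of library. That the tag was joined to RNA without ADPRC, and then enriched, may be the source but was not tested, and no biological explanation was tested.

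AT2G24060 and AT5G53140 were the genes at 4 times or more their unenriched level, and at 100 TPM or more, in each enriched library with ADPRC. They were higher still in enriched libraries without ADPRC, at 66.2 and 45.2 times the unenriched control as means and 36.6 times or more in each library, against means of 26.8 and 14.5 times with ADPRC. A capture that needs no ADPRC reaction is therefore a candidate explanation. Of their reads with ADPRC 17 of 2596 and 1 of 2973 were tagged, at most 0.655% against 19.6% of all reads. Whether their untagged reads covered whole transcripts was not tested. The low share can therefore not by itself exclude capture of tagged molecules. What in these transcripts was captured was not tested, and neither was a biological explanation.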

How the results depend on the processing

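Chosen only after results had been seen were library totals for shares in edgeR and DESeq2, edgeR with the replicate block, camera on the edgeR fit, and the Calvin cycle share without RBCS genes. The change of share under enrichment gave 0 genes with totals and 97 with TMM. TMM and the size factors of DESeq2 had been the first choices for the share tests, until TMM made false calls on simulated data. The counts below are called genes, with higher and lower ones in brackets where both occur, and where no reason is given the cause was not tested. Tagged reads with against without ADPRC after enrichment gave 7384, with 1215 at a mean of 10 TPM (fewer genes tested), 3001 with quantile normalization (1535 and 1466), 4408 with DESeq2 and 7168 with centring (54 and 7114). Tagged reads enriched against unenriched gave 7297, with 1237, 1738 (667 and 1071), 3951 and 6122 (59 and 6063) in that order. All reads with against without ADPRC gave 22 (14 and 8), with 35 at the larger pseudocount, 34 without a filter, 60 at 10 TPM, 51 with quantile normalization (38 and 13), 0 without the trend, 50 with array weights, 96 with edgeR (80 and 16), 58 with DESeq2 (46 and 12) and 38 with all 10 libraries (29 and 9). All reads enriched against unenriched gave 932 (563 and 369), with 1469 at 10 TPM, 37 without the trend and 1453 with edgeR (830 and 623). DESeq2 gave 815 there (370 and 445). Tagged against all reads gave 13506 lower in unenriched libraries, with 5294 at 10 TPM, 4973 with quantile normalization (2365 and 2608), 46 with edgeR (26 and 20), 74 with DESeq2 (65 and 9), 277 with TMM (2 and 275), 12641 with centring (12346 and 295) and 1902 with the size factors of DESeq2 (1 and 1901). In enriched libraries it gave 17088 lower, with 6011, 5508 (3143 and 2365), 4445 (771 and 3674), 2042 (438 and 1604), 4223 (946 and 3277), 6606 (4424 and 2182) and 1898 (620 and 1278) in that order. Quantile normalization sets the overall level equal by construction. Centring sets equal only the median of the genes above 0 in every library of the fit, so the level of all genes can still shift. Genes without a tagged read in 1 side of a comparison then take a direction that rests on the pseudocount. The unenriched control gave 324, with 118 at the larger pseudocount, 112 without a filter, 63 at 10 TPM, 21 with centring, 85 with quantile normalization (46 and 39), 99 with edgeR and 62 with DESeq2. Total against poly(A) RNA gave 6858 (84 and 6774), with 1608 at the larger pseudocount, 4522 without a filter, 1625 at 10 TPM, 1288 with quantile normalization (411 and 877) and 0 with edgeR and DESeq2, where 1 library stands against 3. Without single libraries the counts, for these comparisons in that order, were 7236 to 7347, 6942 to 7194, 0 to 13, 151 to 496, 13487 to 13506, 15798 to 16442, 147 to 210 and 4538 to 7397; a library left alone in a group was assumed to vary like the others.

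Same-numbered replicates did not deviate together by over 0.1 in each pair (r 0.0769 to 0.102 for all reads with and without ADPRC, -0.0135 to 0.00979 for tagged reads, -0.0119 to 0.0371 and 0.00806 to 0.0154 for tagged and all reads under enrichment). The labels give these samples only a shared number, and whether they are paired was not settled. With that number as a replicate block limma called 213 genes (151 and 62) for all reads with and without ADPRC, where every sample correlated best with its own number, a hint from the data and not the design. It called 7410, 7327 and 1045 in the other comparisons of that kind. EdgeR with the replicate block called 4523, 269 (217 and 52), 3847 and 1425 (811 and 614) for tagged and all reads with and without ADPRC and tagged and all reads under enrichment. Without a block, tagged against all reads gave 13475 and 16525.

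Of 97 list tests 47 were called by camera, 0 with an estimated correlation (smallest adjusted p = 0.0797), 72 by fry, 27 with members at 10 TPM or more, 42 without the top 2 members, and 54 and 0 on the edgeR fit with the preset and an estimated correlation (smallest adjusted p = 0.0741). Genes with tagged RNA numbered 6147, with 1472 at 10 TPM, 5025 at 2 reads, 9208 in 2 of 3 libraries, 7371 at 5 times the control and 6274 to 7464 without single libraries. The levels of 10 TPM and 2 reads applied to libraries with and without ADPRC alike. The median share, 0.467% and 18.5%, was 0.320% and 17.0% at 50 TPM and 0.487% and 17.9% at 500 TPM. Without single libraries it was 0.354% to 0.485% and 16.4% to 21.0%, and library shares were 17.5% to 22.4%, 0.176% to 0.222% and 0.566% to 0.665%. PSBW turned to -0.0486 with quantile normalization in the unenriched control. For the 122 named results, 1800 of 2068 values kept direction and call, 267 lost the call and 1 reversed. By number most calls were lost without the trend (39 of 122) and with DESeq2 (34). Leaving out enriched replicates 1, 2 and 3 without ADPRC lost 8, 17 and 18 of 28. Of 290 values of 97 tagged shares 288 stayed within 1 SD. Depth limits tagged values of unenriched and total RNA libraries.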

Other observations

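The tests in this part were chosen only after results had been seen. Exceptions are the share tests with TMM and with the size factors of DESeq2, though their genes were picked then. Genes whose IDs begin with AT2G07 take in a copy of the mitochondrial genome on chromosome 2. They also take in other nuclear genes such as PFD1 (AT2G07340) and CAS1 (AT2G07050). Their tagged shares in enriched libraries with ADPRC varied. AT2G07774 had 74.3% ± 3.92 (SD, n = 3; 106 of 140 reads), AT2G07815 68.2% ± 14.5 (23 of 35), AT2G07695 57.5% ± 9.90 (27 of 47) and AT2G07719 46.8% ± 8.20 (18 of 37). PFD1 had 25.4% ± 8.37 (29 of 114). Low shares were those of AT2G07671 (8 of 86 reads), AT2G07180 (4 of 82), CAS1 (3 of 157) and AT2G07360 (1 of 67). Of the mitochondrial genes ATMG01170 had 49.6% ± 14.6 (28 of 53), while ATMG00020 had 0.795% ± 0.458 (5 of 615) and ATMG00030 0 of 385. Which of these genes lie in the copy was not tested, and the split of reads between copies in nucleus and mitochondrion is uncertain.

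For enrichment without ADPRC, 3 libraries against 1, limma called 228 genes higher and 58 lower of 19871 for all reads (2783 at unadjusted p under 0.05). EdgeR called 67 higher and 90 lower, so neither the count nor its balance held between tools. Relative to the share of the whole library, edgeR placed the tagged share in unenriched libraries of AT5G22580 higher by 3.94 on the log2 scale, the ribosomal protein genes AT4G14320 and AT3G60245 by 3.35 and 3.24, AT5G42530 by 2.78 and the metallothionein gene MT2A by 1.99, with library totals. With TMM AT5G22580 was called at 2.11, and the others, at 1.51, 1.41, 0.97 and 0.15, were not. DESeq2 with its own size factors called none of the 5.

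Other splits of the same libraries were counted for each comparison of 3 libraries with 3. In 1 of 10 splits, the real one, as many genes were called for tagged and all reads with and without ADPRC (7384 and 22, highest other 0 and 1) and for tagged and all reads under enrichment (7297 and 932, highest other 0 and 0). For tagged against all reads it was 1 of 4 splits in unenriched and enriched libraries (13506 and 17088, highest other 0 and 0). The splits are too few for a share under 0.05.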
